A study of Homo sapiens and Mus musculus with 36 samples.

How the data were processed

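Gene expression was measured by RNA sequencing in 36 libraries of 4 tumour cell lines. The deposited values are counts per gene symbol, 1 file per library, which the authors made without a stated normalization. The submitters' notes name Trim Galore, HISAT2 2.2.1, SAMtools 1.9, DESeq2 1.36.0 and the builds hg38 and mm10, without a role or an order for each. The program that counted reads and the annotation are not given in the sources used here. The values were checked to be whole numbers with library totals that differ. The HuH-7 guide files list 26457 symbols, the mouse files 22673 and the DMSO and EPZ-5676 files 15899. In the last set the lowest count is 1, so genes with no read in at least 1 of those 6 libraries are not listed, and no statement is made on them. The sgNeg2 files of Hepa1-6 hold 1721 lines each with no symbol and no count, and those of Hep53.4 hold 1 each, which were dropped.

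Libraries were grouped by line, guide, IFN and drug as the labels give them, in 17 groups of 2 libraries (3 for DMSO and for EPZ-5676). Libraries edited with either guide were pooled as knockout, 4 libraries against 2 sgNeg2 libraries in each of 5 settings. The groups, the comparisons, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined, and the alternatives added later are named as such. Replicate numbers are shared between groups by the labels, but correlations of residuals between libraries of the same number lay between -0.094 and 0.148. The numbers were therefore not taken to pair samples. In DMSO and EPZ-5676 each of the 3 replicates did correlate best with its own number, though weakly (0.08, 0.038 and 0.064). A replicate block was among the alternatives.

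Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and quasi-likelihood fits with robust dispersion were tested by F tests. The 12 HuH-7 guide libraries were fitted together, with genotype, IFN and their interaction as contrasts. The 6 DMSO and EPZ-5676 libraries and the 6 libraries of each mouse line were fitted apart, and the 18 mouse libraries were fitted jointly to test differences of the knockout effect between lines. P-values were adjusted by Benjamini and Hochberg over the genes tested in a comparison, and a gene was called at an adjusted p below 0.05. Each value after a log2 change is its standard error, taken from the F statistic. Levels (CPM) are means of TMM-scaled counts relative to the library total. Where all libraries of a group had no counts, a lower bound of the fold was computed against 3 counts over the group. Such bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

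For each species 28 gene lists were fixed. A list with at least 5 measured members was tested by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. For each list the members that rose or fell are given over all genes tested and as adjusted over the list alone. Calls of 36 of 93 list tests held with an estimated correlation.

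Genes were named by 3 parts of 1 rule. A panel of 20 genes per species was tested in every comparison in which the gene was listed and passed the filter. The 6 largest rises and 6 largest falls were taken among called genes with a mean of at least 5 CPM whose libraries of the compared groups did not overlap and whose guides moved alike, passing over symbols that are not official names. From each list with at least 3 called members or an adjusted p below 0.05, the 3 called members with the largest change were taken for the interferon, chemokine, class I and nucleic acid sensing lists, and 2 for others. A gene named in a comparison may also be given in another. Some genes that this rule names are not reported here, though they are included in the counts.

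Tests were checked on simulated data with 200 changed genes. The simulated libraries shared the same profile apart from these genes. Trends between libraries, other kinds of library and shifts of most genes were therefore not covered. A 2-fold change was recovered for 73.1% of genes in knockout without IFN, 58.2% in IFN in sgNeg2 cells, 61.2% in the interaction, 79.1% with EPZ-5676 and 89.6 to 92.5% in the mouse lines. A 4-fold change was recovered for 74.2% of genes in the interaction and 86.4 to 100% in the other simulated comparisons, and false calls were 1.06 to 7.06% of calls. The share required of this check at a 4-fold change was lowered after the value of the interaction had been seen.

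The alternatives were RLE in place of TMM scaling, DESeq2 1.42.0, no filter, a 2-fold threshold, each library left out in turn, guides apart, smaller or joint fits, a replicate block, and fry in place of camera. Added after the data had been seen were the DMSO libraries as control for IFN, IFN libraries thinned to the depth of those without IFN, a 6-library fit of the guides with IFN, and removal of the trend of each library on transcript length and GC content (10 bins each). A library left alone in its group was assumed to vary like the others. Gene positions, transcript lengths and GC content of human genes were taken from GENCODE release 29 on hg38. No mouse annotation was used, so mouse positions are not given. Scripts ran in R and in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

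Library totals lay between 19580588 and 61227426 counts. Replicates of a group differed by more than counting error, with a mean chi-square per gene between 2.81 and 62.6.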

Results

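The series holds RNA sequencing counts per gene for 36 libraries in 17 groups, from 4 tumour cell lines. HuH-7 is a human hepatocellular carcinoma line, Hepa1-6 and Hep53.4 are mouse liver tumour lines, and LLC is the mouse Lewis lung carcinoma line. In each line the gene for DOT1L, a histone H3 methyltransferase, was edited by CRISPR with guide sg1 or guide sg2, and cells with the control guide sgNeg2 served as the comparison, with 2 libraries per guide. The HuH-7 guide set was sequenced without and with interferon (IFN), whose type, dose and time are not given in the sources used here. HuH-7 cells were also treated with the DOT1L inhibitor EPZ-5676 for 7 days or with its vehicle DMSO, with 3 libraries each. The labels give no time for DMSO. Library totals were 19580588 to 22649969 counts in the HuH-7 guide libraries without IFN, 47594968 to 61227426 in those with IFN, 48912627 to 58628528 in the DMSO and EPZ-5676 libraries and 42637155 to 59686358 in the mouse libraries. Histone genes took 0.827 to 1.00% of the counts in the HuH-7 guide libraries without IFN, 0.0329 to 0.0472% in those with IFN and 0.0300 to 0.0344% in the DMSO and EPZ-5676 libraries. Small nuclear RNA genes took 1.88 to 3.42%, 0.00885 to 0.0106% and 0.0155 to 0.0191% of the counts in the same 3 sets. Here and below this class also holds RMRP, RPPH1 and the genes of small nucleolar and Cajal body RNAs. The labels do not say whether replicates are separate cultures, so they may be technical, and the p-values measure only the spread between these samples.

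DOT1L transcript counts were lower in every edited library than in the sgNeg2 libraries of the same setting. The human gene lies on the plus strand of chromosome 19 of hg38, from 2164149 to 2232578. In HuH-7 without IFN the sgNeg2 libraries held 75.5 and 73.1 CPM (TMM-scaled counts relative to the library total), the sg1 libraries 35.6 and 32.1 CPM, and the sg2 libraries 40.4 and 34.8 CPM. With IFN the sgNeg2 libraries held 108 and 109 CPM, the sg1 libraries 42.5 and 46.5 CPM and the sg2 libraries 66.8 and 66.7 CPM. The log2 change of DOT1L in knockout cells was -1.06 ± 0.16 (SE; edgeR adjusted p = 0.000942) without IFN and -0.97 ± 0.16 (adjusted p = 0.0011) with IFN. Mouse Dot1l went from 43.6 ± 2.95 (SD, n = 2) to 15.7 ± 1.03 CPM (SD, n = 4) in Hepa1-6, from 21.9 ± 0.467 to 13.8 ± 2.02 CPM in Hep53.4 and from 65.4 ± 4.81 to 32.2 ± 1.56 CPM in LLC. The adjusted p values for these falls were 5.23e-12, 6.49e-07 and 1.38e-10. EPZ-5676, which acts on the enzyme, left 49.3 ± 1.76 CPM (SD, n = 3) against 52.9 ± 1.41 CPM (SD, n = 3) with DMSO, a log2 change of -0.10 ± 0.04 (adjusted p = 0.0489). That small fall did not pass the threshold without DMSO replicate 2 (-0.08), DMSO replicate 3 (-0.11), EPZ-5676 replicate 1 (-0.10) or EPZ-5676 replicate 3 (-0.07), nor with DESeq2 (adjusted p = 0.0591).

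**Figure D1:**
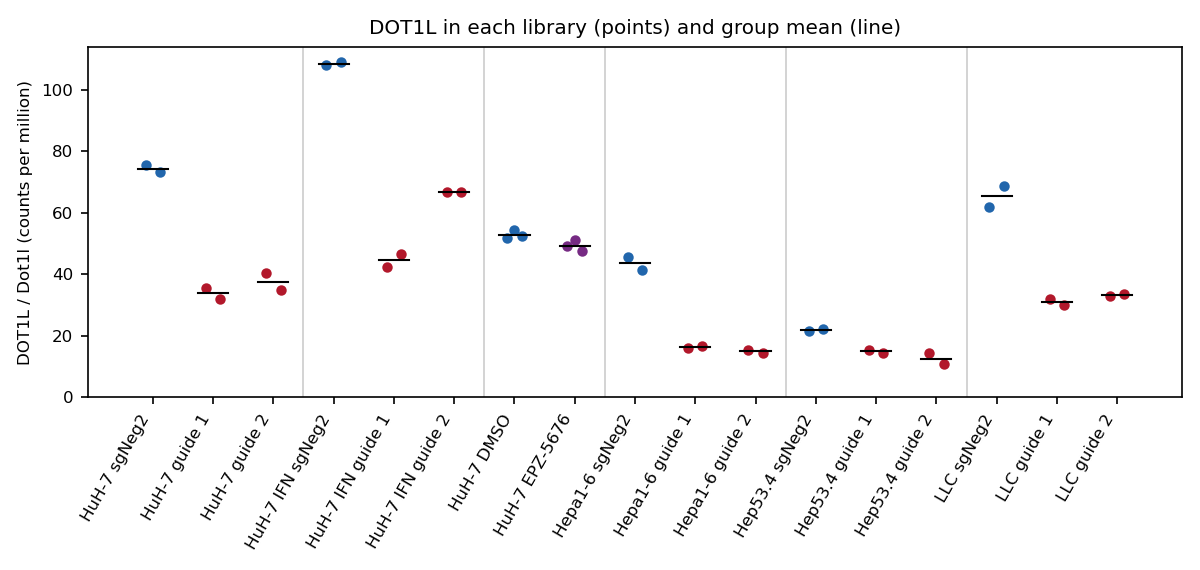
CPM of DOT1L (HuH-7) or Dot1l (mouse lines) on the y axis for each library, as points, by group, with a line at the group mean. Every edited library lies below the sgNeg2 libraries of its setting, from 75.5 and 73.1 CPM to 32.1 to 40.4 CPM in HuH-7 without IFN.

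The comparison of edited with sgNeg2 HuH-7 cells without IFN asks which transcripts depend on DOT1L in this line. HAS2, which encodes a hyaluronan synthase, rose from 0.792 to 9.47 CPM (log2 3.57 ± 0.17, adjusted p = 8.92e-08). SPP1, which encodes osteopontin, rose from 3.04 to 18.9 CPM (log2 2.63 ± 0.12, adjusted p = 8.92e-08). The carcinoembryonic antigen family gene CEACAM7 rose from 0.898 to 13.5 CPM (log2 3.90 ± 0.23, adjusted p = 4.92e-07). CD109, a membrane glycoprotein gene, rose by a log2 of 3.72 ± 0.36, the semaphorin gene SEMA3C by 3.28 ± 0.19 and the long noncoding RNA UCA1 by 2.84 ± 0.17. CD177, a neutrophil surface antigen gene, had 0.0215 CPM (1 count over both sgNeg2 libraries) and 14.9 CPM in knockout cells (adjusted p = 6.01e-07). The homeobox gene HMX3 fell by 1.92 ± 0.18 on the log2 scale (adjusted p = 2.08e-05). ZEB1, a repressor of epithelial genes, fell by 1.45 ± 0.10 (38.4 to 14.1 CPM, adjusted p = 1.24e-06). The organic cation transporter gene SLC22A3 fell by 1.30 ± 0.15, BAHCC1 by 1.29 ± 0.18 and the raftlin gene RFTN1 by 1.28 ± 0.10.

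Interferon and chemokine genes were higher in knockout cells that had received no IFN. Of 56 measured interferon-stimulated genes 22 rose and 0 fell (24 and 0 adjusted over the list alone; camera adjusted p = 6.8e-11). Of 33 interferon gamma response genes 15 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 1.1e-14). The GTPase gene MX1 rose from 2.38 to 7.59 CPM (log2 1.67 ± 0.17, adjusted p = 3.84e-05). IFIH1, which encodes the RNA sensor MDA5, rose from 4.07 to 9.38 CPM (log2 1.20 ± 0.18, adjusted p = 0.000915). The guanylate-binding protein genes GBP5 and GBP4 rose by log2 values of 4.51 ± 0.28 and 2.74 ± 0.31 from levels of 0.0859 and 0.15 CPM. CD274, which encodes PD-L1, rose from 0.172 to 0.881 CPM (log2 2.33 ± 0.35, adjusted p = 0.000914). IFIT3 rose by 0.57 ± 0.10, but did not pass the threshold without sgNeg2 replicate 2 (log2 0.45). ISG15 (log2 -0.10 ± 0.26, adjusted p = 0.852) and IFIT1 (log2 -0.21 ± 0.15, adjusted p = 0.414) did not pass the test. Of 28 chemokine and cytokine genes 13 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 1.49e-12). CXCL10, a T cell attractant, rose from 3.81 to 7.62 CPM (log2 1.00 ± 0.11, adjusted p = 8.16e-05) and CXCL6, a neutrophil attractant, by 1.48.

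Of 19 genes of MHC class I presentation 3 rose, HLA-C, B2M and NLRC5 (12 adjusted over the list alone; adjusted p = 8.09e-05). HLA-C had a log2 of 0.93 ± 0.16 (adjusted p = 0.00179), and B2M, the class I light chain, rose from 52.7 to 83.6 CPM (log2 0.66 ± 0.13, adjusted p = 0.00398), a call that ended without sgNeg2 replicate 2 (log2 0.55). That of NLRC5 (log2 0.67) ended without sgNeg2 replicate 1 (0.63), sgNeg2 replicate 2 (0.66), sg1 replicate 1 (0.55) or sg1 replicate 2 (0.58). HLA-B had a log2 of 0.80 (adjusted p = 0.0588), and passed the test without sg2 replicate 2 (log2 0.95) and with DESeq2 (adjusted p = 0.012). The HLA genes lie in a region of chromosome 6 whose 169 genes had a median of 0.124 CPM in sgNeg2 cells with IFN, against 8.26 CPM for 817 other genes of that chromosome, so their levels in HuH-7 are uncertain.

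Hepatocyte genes moved both ways in the knockout without IFN. Of 38 secreted hepatocyte products 3 rose and 11 fell (4 and 14 adjusted over the list alone; camera adjusted p = 0.000429, and 0.138 as the adjusted p with an estimated correlation). The fibrinogen gene FGA fell from 252 to 121 CPM (log2 -1.06 ± 0.11, adjusted p = 5.16e-05). AHSG, which encodes fetuin-A, rose from 6.53 to 25.1 CPM (log2 1.94 ± 0.20, adjusted p = 5.07e-05). LBP, the lipopolysaccharide-binding protein gene, fell by 1.13 ± 0.09, and CYP2B6, a xenobiotic-metabolising enzyme gene, rose from 0.493 to 2.80 CPM. Of 24 unfolded protein and ATF4 target genes 3 rose and 10 fell (3 and 13 adjusted over the list alone; adjusted p = 0.00236, and adjusted p = 0.106 with an estimated correlation). Of 23 genes of glycolysis and hypoxia 1 rose and 5 fell (1 and 10 adjusted over the list alone; adjusted p = 0.000429, and adjusted p = 0.316 with an estimated correlation). Of 44 ribosomal protein genes 12 fell (21 adjusted over the list alone; adjusted p = 1e-07, and adjusted p = 0.34 with an estimated correlation). RPS2 fell by 0.52 ± 0.13, a call lost without sgNeg2 replicate 1 (-0.51) or replicate 2 (-0.57). Among 28 genes of mesenchymal transition and matrix 7 rose and 5 fell (9 and 5 adjusted over the list alone; adjusted p = 0.648). The collagen gene COL1A1 rose by 1.77 ± 0.28 (adjusted p = 0.00119). Of 6 lung epithelial markers 2 rose (2 adjusted over the list alone; adjusted p = 0.0409, and adjusted p = 0.138 with an estimated correlation), among them CAV1, a gene of caveolae in many cell types, from 11.8 to 27.2 CPM.

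In all, 1143 genes rose and 720 fell of 16448 tested (edgeR quasi-likelihood test, adjusted p below 0.05), 554 and 31 of them by at least 2-fold. With RLE in place of TMM scaling the split was 1056 and 1015, and with guides as groups 2048 and 2160. Without sgNeg2 replicate 1 the count was 564 genes and without sgNeg2 replicate 2 it was 632. The log2 changes followed the GC content of the transcripts (Spearman -0.371 across 11779 genes, which are not independent replicates), as changes between libraries of one setting did. The guides differed by 5 genes, BNIP3 (log2 of sg2 over sg1 0.44), CP (0.37), FGA (0.40), TFRC (0.27) and FOSB (-1.06), named after their values were seen. That number depended on single libraries, since it was 0 without sg1 replicate 1 or sg1 replicate 2 (edgeR), 3688 without sg2 replicate 1 and 96 without sg2 replicate 2. At an unadjusted p under 0.05 the guides differed by 1876 genes, and DESeq2 called 112.

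The same comparison in IFN-treated cells asks what DOT1L loss changes once the interferon response is on. HAS2 rose from 0.519 to 14.0 CPM (log2 4.74 ± 0.16, adjusted p = 4.63e-09), CD177 from 0.153 to 38.3 CPM (log2 7.90 ± 0.38, adjusted p = 5.16e-08), CD109 by 3.90 ± 0.37 and CEACAM7 by 3.86 ± 0.23. IGFBP2 and IGFBP3, which encode carriers of insulin-like growth factors, rose by 4.42 ± 0.29 and 3.97 ± 0.27. IDO1, the tryptophan-degrading enzyme, rose from 1.81 to 22.8 CPM (log2 3.65 ± 0.18, adjusted p = 9.7e-08). The Notch ligand gene JAG1 fell by 1.21 ± 0.06 (322 to 139 CPM, adjusted p = 4.41e-08). TRABD2B fell by 1.81 ± 0.21, the calcium sensor gene VSNL1 by 1.23 ± 0.10, BAHCC1 by 1.15 ± 0.17 and the cysteinyl-tRNA synthetase gene CARS by 1.25 ± 0.20.

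Of 28 chemokine and cytokine genes 18 rose and 0 fell in the IFN-treated knockout (20 and 1 adjusted over the list alone; camera adjusted p = 3.95e-17). CXCL6 rose from 4.98 to 18.9 CPM (log2 1.92 ± 0.16, adjusted p = 3.49e-06) and CXCL10 from 341 to 544 CPM (log2 0.68 ± 0.08, adjusted p = 7.17e-05). Of 33 interferon gamma response genes 14 rose and 1 fell (18 and 3 adjusted over the list alone; adjusted p = 4.16e-09). GBP5 rose from 109 to 360 CPM (log2 1.72 ± 0.08, adjusted p = 4.41e-08) and GBP4 by 1.54 ± 0.10. Of 56 interferon-stimulated genes 12 rose and 1 fell (12 and 3 adjusted over the list alone; adjusted p = 0.0126). MX1 rose from 12.1 to 23.2 CPM (log2 0.93 ± 0.14, adjusted p = 0.000451) and SAMD9 by 1.47 ± 0.24. B2M (log2 0.04 ± 0.12, adjusted p = 0.878), IRF1 (-0.12 ± 0.09, adjusted p = 0.439) and IFIT3 (-0.15 ± 0.08, adjusted p = 0.304) did not pass the test. With a single guide, IFIT3 was lower with sg2 (-0.22), and B2M was higher with sg1 (0.23) and lower with sg2 (-0.18), each past the threshold. Of 16 immune checkpoint and NK ligand genes 5 rose and 0 fell, IDO1, ULBP2, CD47, ARG2 and CD274 (6 and 0 adjusted over the list alone; adjusted p = 3.22e-05). CD274 rose from 9.95 to 14.2 CPM (log2 0.51 ± 0.15, adjusted p = 0.0444), and without any single library of the 6 with IFN it missed the threshold, with log2 values from 0.49 (without sg1 replicate 1 or sg2 replicate 2) to 0.55 (without sg1 replicate 2), through 0.50 and 0.53 (without sgNeg2 replicates 1 and 2) and 0.54 (without sg2 replicate 1). CD47 (log2 0.88) missed it without IFN sgNeg2 replicate 1 (0.78).

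Of 28 matrix genes 8 rose and 3 fell in IFN-treated knockout cells (12 and 3 adjusted over the list alone; camera adjusted p = 4.91e-07). COL1A1 rose from 1.59 to 10.2 CPM (log2 2.67 ± 0.28, adjusted p = 4.05e-05). Among hepatocyte secreted products 11 of 38 rose and 5 fell (14 and 6 adjusted over the list alone; adjusted p = 0.0126, and adjusted p = 0.212 with an estimated correlation), with AHSG up by 2.68 ± 0.20. ACSL1, a fatty acyl-CoA synthetase gene, rose by 1.10 ± 0.12, and the cyclin-dependent kinase inhibitor gene CDKN1A from 20.9 to 43.3 CPM (log2 1.05 ± 0.10, adjusted p = 2.11e-05). Of 44 cell cycle genes 0 rose and 4 fell (0 and 3 adjusted over the list alone; adjusted p = 0.0126). TET1, a DNA demethylation enzyme gene, fell by 0.80 ± 0.11, and MLLT3, a partner of DOT1L in transcription complexes, by 0.69 ± 0.11. Of 13 leukocyte markers 2 rose (5 rose and 1 fell adjusted over the list alone; adjusted p = 0.00759). The lysozyme gene LYZ rose from 85.4 to 233 CPM (log2 1.45 ± 0.11). Lung epithelial markers were higher as a set (1 of 6 rose; 2 adjusted over the list alone; adjusted p = 0.00382), with CAV1 up by 1.87 ± 0.13, and of 5 fibroblast markers 3 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.00759, and adjusted p = 0.0667 with an estimated correlation). In the sgNeg2 libraries without IFN the leukocyte markers had a median of 0.151 CPM and 2 of 21 reached 5 CPM, the higher being CD68 at 50.9 CPM.

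With IFN, 1170 genes rose and 867 fell, 735 and 68 of them by at least 2-fold. The balance of rises and falls depended on the fit, with 1596 and 2586 for guides as groups, 1640 and 2719 with sg1 alone, 1833 and 3236 with sg2 alone and 815 and 185 in a 6-library fit. Without IFN sgNeg2 replicate 1 the count was 978 and without IFN sgNeg2 replicate 2 it was 960. The guides differed by 5657 genes with IFN, 2663 without IFN sg1 replicate 1 and 2369 without IFN sg2 replicate 2. The calls without and with IFN had 646 rises and 303 falls in common, where independent lists would give 81.3 and 38.0, and 10 genes were called in opposite directions. Log2 changes of the guides correlated across genes with a Pearson r of 0.824 without IFN and 0.747 with IFN. Simulated unchanged guides that share their controls gave 0.497 and 0.524. The simulated libraries had no trend on GC content, while both real guides take in any trend of their common controls. The excess over the simulated values is therefore no measure of agreement alone. With IFN both guides called 1067 rises and 916 falls in common, and 139 genes were called in opposite directions.

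The comparison of IFN-treated with untreated sgNeg2 cells gives the interferon response of HuH-7. The transcription factor gene IRF1 rose from 29.6 to 276 CPM (log2 3.22 ± 0.12, adjusted p = 9.91e-11). CXCL10 rose from 3.81 to 341 CPM (log2 6.48 ± 0.12, adjusted p = 2.55e-13). GBP5 rose from 0.0859 to 109 CPM (log2 10.26 ± 0.18), the chemokine gene CXCL9 from 0.106 to 220 CPM (log2 10.96 ± 0.28), CXCL11 by 7.93 ± 0.28 and BST2, which encodes the antiviral protein tetherin, by 7.45 ± 0.20. TRIM22, OAS2 and IDO1 had no counts in untreated cells and were at least 228-fold, 72.3-fold and 28.2-fold higher with IFN. CD274 rose from 0.172 to 9.95 CPM (log2 5.83 ± 0.29, adjusted p = 2.81e-09), B2M from 52.7 to 389 CPM (log2 2.88 ± 0.15) and NLRC5, the activator of class I genes, by 3.90 ± 0.19. IFIT1 had a log2 of 0.40 ± 0.17 (adjusted p = 0.0506), which passed the threshold without sgNeg2 replicate 1 (0.54) and was -0.15 against DMSO (adjusted p = 0.265). DOT1L itself had a log2 of 0.55 ± 0.19 (adjusted p = 0.0194), a call lost without sgNeg2 replicate 1 (0.58), sgNeg2 replicate 2 (0.47), IFN sgNeg2 replicate 1 (0.55) or IFN sgNeg2 replicate 2 (0.55). Against DMSO the log2 of DOT1L was 0.97 ± 0.04 (edgeR adjusted p = 3.28e-18), and DMSO against sgNeg2 had -0.47 for it.

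Of 33 interferon gamma response genes 27 rose with IFN and 0 fell (27 and 0 adjusted over the list alone; camera adjusted p = 3.08e-54), and of 56 interferon-stimulated genes 45 rose and 4 fell (47 and 4 adjusted over the list alone; adjusted p = 5.68e-22). Of 19 class I presentation genes 19 rose (19 adjusted over the list alone; adjusted p = 6.63e-18). In all 5430 genes rose and 5715 fell, and the largest falls were RNA species other than polyadenylated messengers. RN7SK, a small nuclear RNA, went from 13000 to 0.573 CPM, RMRP from 10900 to 0.0668 CPM, and the histone gene HIST1H3F was at least 4560-fold lower. The libraries without IFN differ from those with IFN in depth and in these RNA classes, so the DMSO libraries, which resemble the IFN libraries in both, were taken as another control after the data had been seen. Against both controls 3996 genes rose and 3284 fell, and 825 were called in opposite directions, of 15161. Interferon gamma response genes rose against both in 22 of 28 cases, interferon-stimulated genes in 40 of 48 (1 fell against both), class I genes in 15 of 17, chemokines in 14 of 23 (2 fell against both) and checkpoint genes in 8 of 12. Against DMSO the log2 values of GBP5, BST2, CXCL10 and CD274 were 10.92, 8.31, 6.45 and 6.42, while that of RN7SK was 0.65 (adjusted p = 0.345). TRIM22 had a log2 of 6.01 against DMSO, and DMSO lay above sgNeg2 by 6.21 for it, so its bound against sgNeg2 holds for that control only. Secreted hepatocyte products fell against both controls in 19 of 36 cases, and ribosomal protein genes had a median log2 of 0.86 against sgNeg2 but -0.06 against DMSO.

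In DOT1L knockout cells IFN raised the same families. CXCL9 rose from 0.285 to 297 CPM (log2 10.01 ± 0.18, adjusted p = 4.96e-14), GBP5 from 2.03 to 360 CPM (log2 7.47 ± 0.09, adjusted p = 1.1e-15) and CXCL10 from 7.62 to 544 CPM (log2 6.16 ± 0.08). Of 33 interferon gamma response genes 29 rose and 1 fell (29 and 1 adjusted over the list alone; camera adjusted p = 6.05e-53). Of 56 interferon-stimulated genes 48 rose and 5 fell (48 and 5 adjusted over the list alone; adjusted p = 2.48e-18). In all 5994 genes rose and 6939 fell, between libraries that differ in depth and in RNA classes as those of sgNeg2 cells do.

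The interaction of genotype and IFN asks whether the response to IFN itself differed in knockout cells. A lower response in knockout cells can come from a higher level without IFN, and need not mean a lower level with IFN. GBP5 was higher in knockout than in sgNeg2 cells both without IFN (log2 4.51) and with IFN (log2 1.72). BST2 stood at 237 CPM with IFN in sgNeg2 cells and 240 CPM in knockout cells, and its response was lower in knockout cells by a log2 difference of -2.29 ± 0.23 (adjusted p = 0.000532). ENTPD1, which encodes the ectonucleotidase CD39, had a difference of -2.23 ± 0.18 (adjusted p = 0.000144). GBP5 had a difference of -2.79 ± 0.34 (adjusted p = 0.00209) and the galectin-3 binding protein gene LGALS3BP one of -1.69 ± 0.22 (adjusted p = 0.00328), which did not pass the threshold without sgNeg2 replicate 2 (-2.12 and -1.49). Of 33 interferon gamma response genes 7 had a negative difference and 0 a positive one (13 and 0 adjusted over the list alone; camera adjusted p = 8.29e-11). Of 56 interferon-stimulated genes 6 had a negative difference and 0 a positive one (17 and 0 adjusted over the list alone; adjusted p = 1.82e-09). Values for CD274 (-1.81 ± 0.40, adjusted p = 0.0694) and CXCL10 (-0.32 ± 0.13, adjusted p = 0.328) did not pass the test, though CD274 did without sg1 replicate 1 (-1.88).

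A positive difference of the log2 changes with IFN (knockout minus sgNeg2) was found for the fibrinogen genes FGB (1.78 ± 0.19, adjusted p = 0.000618) and FGA (1.68 ± 0.16, adjusted p = 0.000468), the Wnt inhibitor gene DKK1 (1.58 ± 0.15, adjusted p = 0.000442) and NYNRIN (1.63 ± 0.20, adjusted p = 0.00209). All of these fell with IFN in sgNeg2 cells, FGB by 1.22, DKK1 by 2.61 and NYNRIN by 2.91, while in knockout cells DKK1 and NYNRIN fell by 1.04 and 1.28 and FGB rose by 0.55. Each of these changes sets libraries that differ in depth and in RNA classes against each other, so it cannot be ascribed to IFN alone. Of 38 secreted hepatocyte products 4 had a positive difference (7 adjusted over the list alone; camera adjusted p = 1.85e-13). Of 28 matrix genes 1 had a positive difference, ZEB1 with 0.99 ± 0.14 (8 adjusted over the list alone; adjusted p = 5.58e-08), whose call ended without sgNeg2 replicate 2 (1.01) or IFN sgNeg2 replicate 2 (0.94). In all 34 genes had a positive and 49 a negative difference, and 42 and 33 with RLE scaling. The differences of the response followed GC content (Spearman 0.448 across 11779 genes, which are not independent replicates). With the trend on length and GC removed, a fit chosen after the data had been seen, 18 of 56 interferon-stimulated genes had a negative difference and 0 a positive one, with a median log2 of -0.24 (-0.23 before). For the gamma response list these were 16 and 1 of 33, with a median of -0.47 (-0.44 before). In that fit 366 genes had a positive and 735 a negative difference, and CD274 passed the test (-1.64, adjusted p = 0.0284). Single libraries moved the total of 83 to 30 and 19 (without sgNeg2 replicates 1 and 2), 48 and 48 (sg1 replicates 1 and 2), 30 and 30 (IFN sgNeg2 replicates 1 and 2) and 176 (IFN sg1 replicate 1).

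Treatment with EPZ-5676 asks what inhibiting the enzyme does in unedited HuH-7 cells. CXCL10 rose from 3.70 to 13.5 CPM (log2 1.87 ± 0.12, adjusted p = 2.04e-19), CXCL6 from 2.69 to 9.52 CPM (log2 1.83 ± 0.18, adjusted p = 3.61e-07) and CXCL8, which encodes interleukin-8, from 4.24 to 12.5 CPM (log2 1.56 ± 0.11, adjusted p = 8.23e-21). The pantetheinase gene VNN2 rose by 1.79 ± 0.08, PIGR, the polymeric immunoglobulin receptor gene, from 15.3 to 45.1 CPM and the tubulin gene TUBB2B from 11.7 to 31.9 CPM. The tight junction gene TJP1 fell by 0.67 ± 0.08, the polarity gene PARD3B by 0.65 ± 0.05, the vitamin D binding protein gene GC by 0.61 ± 0.05 and APBB2 by 0.59 ± 0.03.

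Of 23 chemokine and cytokine genes 17 rose and 1 fell with EPZ-5676 (18 and 1 adjusted over the list alone; camera adjusted p = 4.11e-13). Of 28 interferon gamma response genes 17 rose and 3 fell (17 and 3 adjusted over the list alone; adjusted p = 1.07e-06). Of 48 interferon-stimulated genes 20 rose and 8 fell (20 and 8 adjusted over the list alone; adjusted p = 0.0247, and adjusted p = 0.153 with an estimated correlation). BST2 rose by 2.03 ± 0.25 (adjusted p = 7.32e-10), the caspase gene CASP1 by 2.02 ± 0.31 and MX1 from 0.859 to 1.73 CPM (log2 1.01 ± 0.26, adjusted p = 0.00158). ISG15 fell by 0.39 ± 0.13 (adjusted p = 0.0145), a call that ended without EPZ-5676 replicate 3 (-0.32). CD274 rose from 0.112 to 0.474 CPM (log2 2.10 ± 0.56, adjusted p = 0.00214), one of 6 checkpoint and NK ligand genes of 12 that rose (7 adjusted over the list alone; adjusted p = 0.0266, and adjusted p = 0.23 with an estimated correlation). Of 17 class I genes 6 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.0307, and adjusted p = 0.17 with an estimated correlation), with NLRC5 up by 0.68 ± 0.17. B2M had a log2 of 0.45 ± 0.15 (adjusted p = 0.0987) and passed the test without EPZ-5676 replicate 3 (log2 0.30) and with DESeq2 (adjusted p = 0.0138).

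Of 22 genes of glycolysis and hypoxia 18 fell with EPZ-5676 and 1 rose (18 and 1 adjusted over the list alone; camera adjusted p = 1.47e-13). PFKFB4, a regulator of glycolysis, fell from 123 to 94.9 CPM (log2 -0.37 ± 0.03, adjusted p = 2.02e-20). Of 19 genes of DOT1L complexes 13 fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 0.0026, and adjusted p = 0.146 with an estimated correlation). Of 44 cell cycle genes 18 fell and 6 rose (19 and 6 adjusted over the list alone; adjusted p = 0.0366, and adjusted p = 0.169 with an estimated correlation). COL1A1 rose by 1.78 ± 0.20, the matrix gene TGFBI by 1.20 ± 0.09, the homeobox gene HOXD13 by 1.47 ± 0.20, ACSL1 by 0.85 ± 0.04, SPP1 by 0.83 ± 0.12 and CDKN1A by 0.59 ± 0.07. TET1 fell by 0.56 ± 0.04. The leukocyte marker LYZ rose from 83.7 to 170 CPM (log2 1.02 ± 0.03), 1 of 4 such markers of 11 that rose (4 adjusted over the list alone; adjusted p = 0.0366, and adjusted p = 0.183 with an estimated correlation). In all 2274 genes rose and 2793 fell of 15023 tested, 415 and 14 of them by at least 2-fold, and the median size of a called log2 change was 0.19. The DMSO and EPZ-5676 counts list only genes seen in each of those 6 libraries, so genes switched on or off by the drug are not among them.

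Knockout and inhibitor were compared gene by gene over 14868 genes measured in both, with no library in common. Genes called in both rose together in 705 cases and fell together in 484, where independent lists would give 161 and 134, and 34 were called in opposite directions, where independent lists would give 307. Log2 changes correlated with a Pearson r of 0.541 and a Spearman rho of 0.483 across genes, which are not independent replicates. HAS2 rose by 3.57 with knockout, 4.74 with knockout under IFN and 3.26 with EPZ-5676, IGFBP3 by 3.11, 3.97 and 2.29 and LYZ by 1.56, 1.45 and 1.02, while JAG1 had values of -0.71, -1.21 and -0.41. In all 3 settings 485 genes rose and 252 fell, where independent lists would give 11.2 and 7.73.

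**Figure D2:**
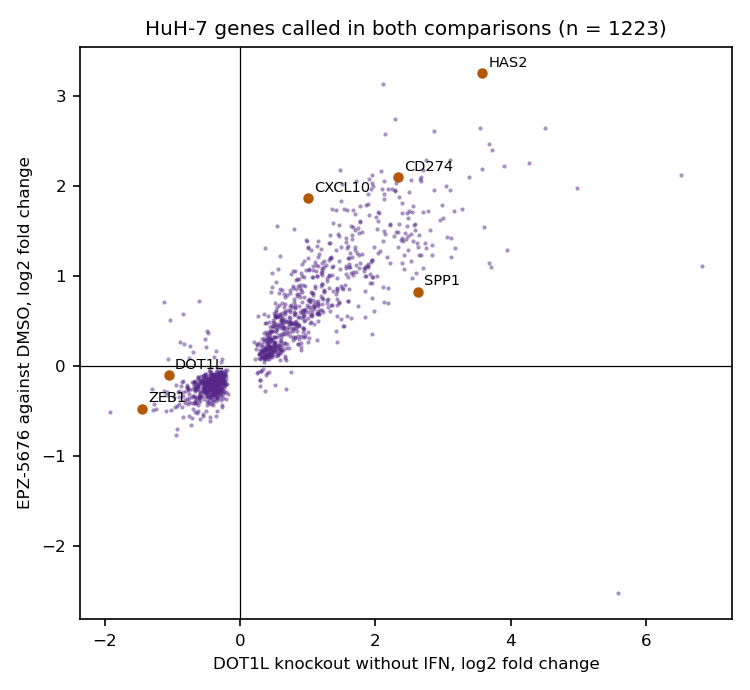
Log2 change with EPZ-5676 (y axis) against log2 change with DOT1L knockout without IFN (x axis) for the 1223 genes called in both comparisons, 1 point per gene, with 6 genes labelled. HAS2, SPP1, CD274 and CXCL10 lie above 0 on both axes, and 34 points lie in the quadrants of opposite sign.

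The mouse lines ask whether Dot1l loss acts alike in other tumour cells. In Hepa1-6, the trefoil factor gene Tff3 rose from 7.95 to 24.5 CPM (log2 1.63 ± 0.12, adjusted p = 3.59e-10) and the surface antigen gene Ly6c1 from 19.6 to 48.6 CPM (log2 1.31 ± 0.09, adjusted p = 1.6e-09). Serpinb9b rose by 1.29 ± 0.16, the matrix gene Thbs2 by 1.19 ± 0.11, Wfdc12 by 1.19 ± 0.14 and the interferon-inducible gene Mndal by 1.16 ± 0.13. Prox1, a transcription factor of hepatocyte and lymphatic development, fell by 1.12 ± 0.06 (71.9 to 33.2 CPM, adjusted p = 2.78e-12). The Wnt inhibitor gene Wif1 fell by 1.12 ± 0.06, the zinc finger gene Zbtb20, a repressor of alpha-fetoprotein, by 1.18 ± 0.13, Tnr by 1.06 ± 0.07 and Pcdhgc5 by 1.01 ± 0.08. Of 62 interferon-stimulated genes 36 rose and 4 fell (40 and 5 adjusted over the list alone; camera adjusted p = 4.82e-09). Isg15 rose from 22.7 to 32.3 CPM (log2 0.51 ± 0.08, adjusted p = 2.36e-05), Irf7 from 160 to 212 CPM (log2 0.40 ± 0.04), Mx1 by 1.00 ± 0.21 and Cxcl10 by 0.32 ± 0.05, and Ifitm1, with no counts in sgNeg2 cells, was at least 12.5-fold higher. Irf1 fell by 0.31 ± 0.04 (adjusted p = 8.83e-06), and the class I genes B2m (-0.11 ± 0.08) and H2-D1 (-0.03 ± 0.04) did not pass the test, B2m passing it with guide sg2 alone (-0.22, adjusted p = 6.22e-07).

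Chemokine genes rose in 7 of 23 cases and fell in 3 in Hepa1-6 (camera adjusted p = 0.0522), with the neutrophil attractant gene Cxcl5 up from 34.1 to 74.1 CPM (log2 1.12 ± 0.11, adjusted p = 5.49e-05). Secreted hepatocyte products fell in 11 of 27 cases and rose in 2 (12 and 2 adjusted over the list alone; adjusted p = 3.98e-05, and adjusted p = 0.363 with an estimated correlation). The inter-alpha-trypsin inhibitor gene Itih2 fell from 1240 to 679 CPM (log2 -0.87 ± 0.04, adjusted p = 7.87e-13). The fetal liver marker Gpc3 fell by 0.44 ± 0.03 (838 to 618 CPM). Genes of DOT1L complexes fell in 10 of 18 cases and rose in 3 (10 and 3 adjusted over the list alone; adjusted p = 0.000216, and adjusted p = 0.134 with an estimated correlation), among them Ccnt1, a subunit of the elongation factor P-TEFb, by 0.70 ± 0.08. Of 43 ribosomal protein genes 20 rose (21 adjusted over the list alone; adjusted p = 0.000322, and adjusted p = 0.535 with an estimated correlation). Of 29 fatty acid metabolism genes 3 rose and 10 fell (3 and 10 adjusted over the list alone; adjusted p = 0.0301, and adjusted p = 0.347 with an estimated correlation), and the list's median (-0.066) and mean (0.023) differed in sign. In all 1811 genes rose and 2284 fell of 12493 tested, and 2381 were called without sgNeg2 replicate 1.

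In Hep53.4, the aldehyde dehydrogenase gene Aldh1a7 rose from 2.24 to 11.5 CPM (log2 2.36 ± 0.13, adjusted p = 7.07e-15). The aldo-keto reductase genes Akr1b7 and Akr1c18 rose by 1.70 ± 0.10 and 1.53 ± 0.07 and the glutathione transferase gene Gstm7 by 1.55 ± 0.11, while Cav1 rose by 1.48 ± 0.13. The integrin gene Itga2 fell by 1.16 ± 0.06 (43.4 to 19.4 CPM, adjusted p = 5.72e-15). Crisp1 fell by 1.24 ± 0.12, the matrix protease gene Mmp10 by 0.87 ± 0.09 and the protocadherin gene Pcdh7 by 0.85 ± 0.09. Of 43 ribosomal protein genes 39 rose (40 adjusted over the list alone; camera adjusted p = 2.9e-11, and adjusted p = 0.306 with an estimated correlation). Rps2 rose from 6090 to 7630 CPM (log2 0.33 ± 0.02, adjusted p = 2.21e-12). Of 24 cholesterol synthesis genes 16 rose (16 adjusted over the list alone; adjusted p = 6.95e-09, and adjusted p = 0.213 with an estimated correlation). Of 24 unfolded protein and ATF4 target genes 5 rose and 9 fell (6 and 9 adjusted over the list alone; adjusted p = 0.0274, and adjusted p = 0.213 with an estimated correlation), and Atf4 itself fell by 0.54 ± 0.03.

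Of 28 p53 targets 14 rose and 2 fell in Hep53.4 (14 and 2 adjusted over the list alone; camera adjusted p = 0.00338, and adjusted p = 0.213 with an estimated correlation), with Cdkn1a up from 306 to 442 CPM (log2 0.53 ± 0.03, adjusted p = 6.84e-14). Of 35 DNA repair genes 12 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 0.0216, and adjusted p = 0.213 with an estimated correlation). Interferon-stimulated genes rose in 11 of 49 cases and fell in 8 (adjusted p = 0.699). Several panel genes had few counts in the sgNeg2 libraries of this line. Isg15 stood at 0.131 and 0.0342 CPM, Ifit1 at 0.112 and 0.0342 CPM and Mx1 at 0.131 and 0.12 CPM. Irf1 stood at 17.9 and 18.7 CPM. An effect on the genes with few counts could therefore not be seen. Ifih1 rose by 0.89 ± 0.16 (adjusted p = 5.11e-05), the peptide transporter gene Tap1 by 0.98 ± 0.21 and the class I gene H2-K1 by 0.16 ± 0.04, the chemokine gene Ccl7 rose by 2.60 ± 0.35, and the nucleotide hydrolase gene Samhd1 fell by 0.61 ± 0.05. In all 2378 genes rose and 2411 fell of 12227 tested.

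In LLC, the thrombospondin gene Thbs1 rose from 5.92 to 21.0 CPM (log2 1.83 ± 0.09, adjusted p = 1.27e-11) and Prss35 from 17.9 to 62.7 CPM (log2 1.81 ± 0.06, adjusted p = 3.91e-14). Igfbp5 rose by 1.75 ± 0.14, the water channel gene Aqp1 by 1.75 ± 0.15, the transglutaminase gene Tgm2 by 1.58 ± 0.15 and the intermediate filament gene Prph by 1.57 ± 0.13. The transcription factor gene Tfap2a fell by 1.00 ± 0.06 (68.1 to 34.1 CPM, adjusted p = 1.68e-10). Usp43 fell by 1.08 ± 0.11 and Nptxr by 0.93 ± 0.12. The homeobox genes Hoxa10 and Hoxd10 fell by 0.88 ± 0.08 and 0.82 ± 0.06, 2 of 6 homeobox genes of 21 that fell (6 adjusted over the list alone; camera adjusted p = 0.00209, and adjusted p = 0.118 with an estimated correlation). Of 23 unfolded protein and ATF4 target genes 17 fell and 2 rose (17 and 2 adjusted over the list alone; adjusted p = 5.91e-10). Chac1, a glutathione-degrading enzyme gene, fell by 1.04 ± 0.08 and Ddit3, which encodes CHOP, from 32.6 to 17.8 CPM (log2 -0.88 ± 0.08, adjusted p = 1.75e-07). Of 43 ribosomal protein genes 38 fell (39 adjusted over the list alone; adjusted p = 6.44e-12, and adjusted p = 0.457 with an estimated correlation). Rpl3 fell from 4350 to 3440 CPM (log2 -0.34 ± 0.05, adjusted p = 7.75e-05).

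Of 44 cell cycle genes 29 rose and 2 fell in LLC (31 and 4 adjusted over the list alone; camera adjusted p = 8.85e-06, and adjusted p = 0.404 with an estimated correlation). The centromere gene Cenpf rose by 0.40 ± 0.06 and Cdkn1a, an inhibitor of the cycle, by 0.77 ± 0.06 (adjusted p = 2.91e-08). Of 53 interferon-stimulated genes 14 rose and 5 fell (14 and 6 adjusted over the list alone; adjusted p = 0.0336, and adjusted p = 0.18 with an estimated correlation), with Ifi203 up from 0.398 to 2.03 CPM (log2 2.34 ± 0.27). Irf1 rose by 0.50 ± 0.09 (adjusted p = 0.000201), B2m fell by 0.26 ± 0.05 (569 to 475 CPM, adjusted p = 0.000159) and H2-D1 by 0.19 ± 0.04. Of 8 fibroblast markers 6 rose (7 adjusted over the list alone; adjusted p = 3.34e-06, and adjusted p = 0.079 with an estimated correlation), and in sgNeg2 cells the most abundant of these markers was Col3a1 with 980 CPM. In all 1957 genes rose and 2140 fell of 12225 tested, and 2519 were called without sgNeg2 replicate 1.

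**Figure D3:**
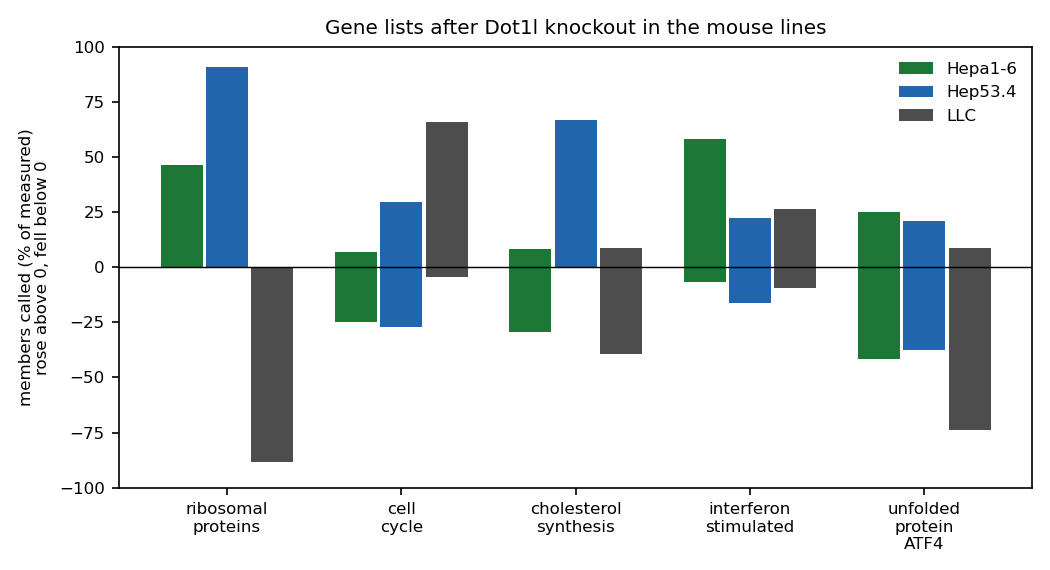
Percentage of measured list members that rose or fell with Dot1l knockout (y axis) in Hepa1-6, Hep53.4 and LLC for 5 gene lists, as bars. Ribosomal protein genes rose in 39 of 43 cases in Hep53.4 and fell in 38 of 43 cases in LLC, both without a list call at an estimated correlation.

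**Figure D4:**
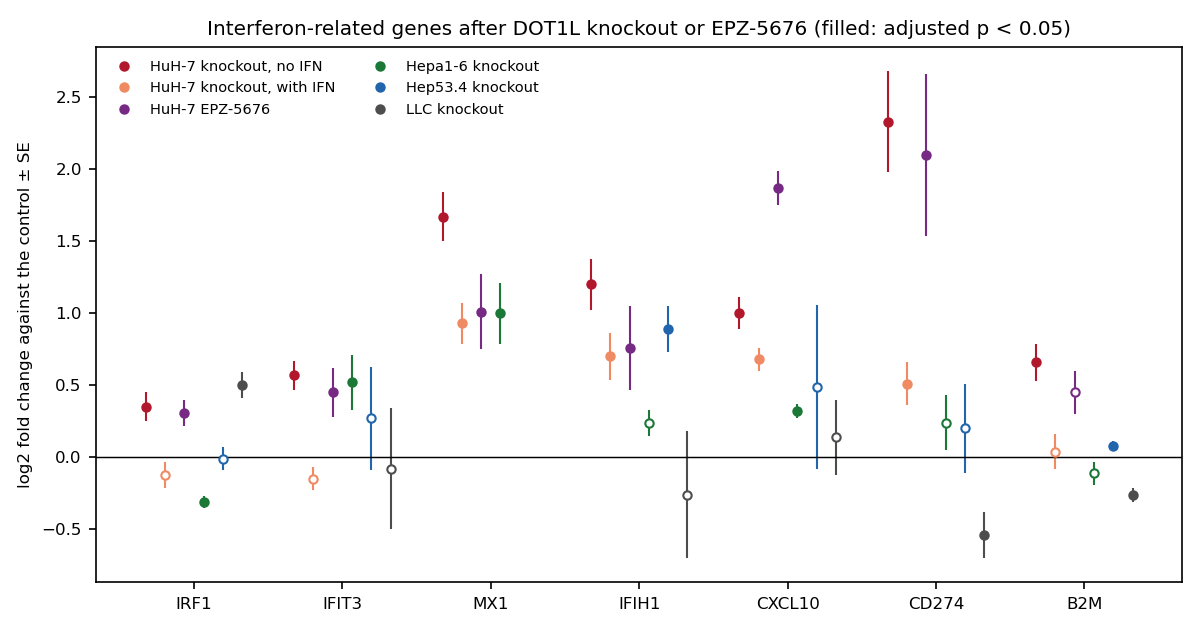
Log2 change ± SE (y axis) of IRF1, IFIT3, MX1, IFIH1, CXCL10, CD274 and B2M, or their mouse counterparts, with DOT1L knockout in 5 settings or with EPZ-5676, as points by gene, filled where the adjusted p is below 0.05. CXCL10 lies above 0 in the 3 HuH-7 settings, with values of 1.00, 0.68 and 1.87 for knockout without IFN, knockout with IFN and EPZ-5676.

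The knockout effect differed among the mouse lines for 5982 of 14195 genes in a joint fit of the 18 mouse libraries (F test over both interaction terms). Transcript length and GC content were not taken for mouse genes, so a trend on them, found in HuH-7, was not tested here. The effect on ribosomal protein genes was higher in Hepa1-6 than in LLC for 36 of 43 genes (39 adjusted over the list alone; camera adjusted p = 3.23e-20, and adjusted p = 0.195 with an estimated correlation) and higher in Hep53.4 than in LLC for 38 of 43 (38 adjusted over the list alone; adjusted p = 6.35e-19, and adjusted p = 0.148 with an estimated correlation). The effect on cholesterol synthesis genes was higher in Hep53.4 than in LLC for 14 of 24 genes (14 adjusted over the list alone; adjusted p = 1.31e-06, and adjusted p = 0.112 with an estimated correlation), and lower in Hepa1-6 than in Hep53.4 for 14 of 24 (17 adjusted over the list alone; adjusted p = 7.69e-07, and adjusted p = 0.0918 with an estimated correlation). The effect on cell cycle genes was lower in Hepa1-6 than in LLC for 20 of 44 genes (23 adjusted over the list alone; adjusted p = 4.21e-06). For interferon-stimulated genes Hepa1-6 had the higher effect for 11 of 64 genes and the lower effect for 6 when set against Hep53.4 (adjusted p = 0.136). Some of these genes, such as Isg15, Ifit1 and Mx1, had few counts in Hep53.4, where their knockout effect is uncertain. Genes called in both Hepa1-6 and Hep53.4 rose together in 541 cases and fell together in 704, where independent lists would give 331 and 455, and 685 were called in opposite directions (782 if independent). For Hepa1-6 and LLC these numbers were 344 and 604 (252 and 396 if independent), with 536 in opposite directions (634 if independent). For Hep53.4 and LLC they were 312 and 337 (340 and 429 if independent), with 1296 in opposite directions (766 if independent). With DESeq2 opposite calls numbered 599 for Hepa1-6 and Hep53.4 (554 if independent) and 489 for Hepa1-6 and LLC (474 if independent), so their relation to independence depended on the test. For Hep53.4 and LLC DESeq2 gave 282 and 293 calls together (263 and 276 if independent), with 1148 in opposite directions (541 if independent). In all 3 lines 87 genes rose and 156 fell of 10564, where independent lists would give 47.4 and 84.7. Of these, 2 rose at least 2-fold in each line, Btn1a1 (1.73, 1.54 and 1.66 in Hepa1-6, Hep53.4 and LLC) and Ifi203 (1.14, 1.06 and 2.34), named after their values were seen, and the call of Ifi203 in Hep53.4 ended without Hep53.4 sgNeg2 replicate 2 (0.61). The guides differed by 348 genes in Hepa1-6, 355 in Hep53.4 and 735 in LLC. Leaving out a guide library lowered these counts to between 116 and 170 in Hepa1-6 (each of the 4) and to between 227 and 395 in LLC (each of the 4). In Hep53.4 they were 50 and 58 without sg1 replicates 1 and 2 and 88 without sg2 replicate 2.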

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

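Chosen after their results were seen were the tests of the kind of library over all called genes, of the length and GC trend, of thinning and of the trend-removed comparison between guides, and both tests of the MHC region; the other tests were set before.

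In each of 5 settings the 4 knockout libraries were compared on several measures, 100 tests in all. In 7 of them a library lay far from the other 3, where chance gives about 1 in 20 of independent tests, which these are not. HuH-7 sg2 replicate 2 had a small nuclear RNA share of 1.88% (others 2.84 to 2.97%), IFIT3 at 11.5 CPM (9.97 to 10.2) and MX1 at 9.49 CPM (6.79 to 7.17). HuH-7 IFN sg2 replicate 1 had 17728 symbols detected (17412 to 17431). Hepa1-6 sg1 replicate 2 had a small nuclear RNA share of 0.0255% (0.00173 to 0.00223%) and Cd274 at 3.39 CPM (4.43 to 4.62). Hep53.4 sg2 replicate 2 had H2-D1 at 47.3 CPM (50.8 to 51.2).

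Effects that differed between groups by a test of the difference were the response to IFN between knockout and sgNeg2 cells (83 genes) and the knockout effect among the mouse lines (5982 genes by F test). By pairs of lines the knockout effect differed for 3506 genes between Hepa1-6 and Hep53.4, 3493 between Hepa1-6 and LLC and 4151 between Hep53.4 and LLC.

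The 1st pattern is that most genes were called for IFN in sgNeg2 cells, while libraries without IFN differ from all other HuH-7 libraries in depth and in histone and small nuclear RNA. DMSO was set against sgNeg2 without IFN, where no library had IFN, with the IFN effect taken from 1 sgNeg2 library and the DMSO difference from the other. The same sign was found for 84.8% of 9062 and 85.6% of 8880 called genes (50.1 and 50% if independent), so a different kind of library may account for much of that count. It does not account for the rise of the interferon lists as a set, since the 62 list members that rose with IFN by a median of 2.72 had a median of -0.63 in DMSO against both sgNeg2 libraries (quartiles -1.16 and -0.03), though single members such as TRIM22 (6.21) differ. For genes outside these lists, IFN and the kind of library remain open, and the labels give no batch.

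The 2nd pattern is that the guides differed by 5657 genes in HuH-7 with IFN. Changes between guides followed GC content (Spearman 0.825 across 11756 genes, which are not independent replicates), and with the length and GC trend removed 1935 genes were called in a 6-library fit, against 7054 before. Of 6793 of those 7054 that were tested again, 1226 were called in the same direction and 223 in the opposite one, so this trend may account for most of them, while depth does not, since 5014 genes were called after thinning. A weaker knockout with sg2 may contribute. With IFN DOT1L stood at 66.8 and 66.7 CPM with sg2 against 42.5 and 46.5 CPM with sg1. Without IFN it stood at 40.4 and 34.8 CPM with sg2 against 35.6 and 32.1 CPM with sg1. Of 477 genes 71.3% differed between guides against the direction of the knockout effect without IFN. That share cannot tell a weaker knockout from the trend, since this knockout effect followed GC content the other way (Spearman -0.371). With the trend removed from both comparisons this share was 65.4% of 700 genes, only just over the bound of 65% it was held to.

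The 3rd pattern is the low level of genes of the MHC region on chromosome 6 in HuH-7. Their median rank lay -31.3 percentage points from that of the same symbols in the mouse lines (116 genes, against 3.28 for 710 other genes of the chromosome), so reads lost to near-identical copies of the region may account for it. RPS18, a ribosomal protein gene of the region, had 10.0 CPM against a median of 916 CPM for 43 other ribosomal protein genes, and mouse Rps18 had 2450 CPM against 1630. Its value cannot tell lost reads from low transcription, and the bound for it was reset after the value had been seen, because the range of the other genes (lowest 7.44 CPM) decided nothing. Low transcription in HuH-7 therefore stays open.

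Other splits of the same libraries were tried for comparisons with at least 3 libraries a side. For EPZ-5676 the real split gave 5067 genes and the highest of the others 1, with as many genes in 1 of 10 splits, which are too few for a share under 0.05. For IFN in knockout cells 1 of 35 splits gave as many genes, the real split with 12067 in an 8-library edgeR fit and the highest of the others with 0. The real split also divides the kinds of library, which all other splits mix. The test therefore shows only that the libraries with and without IFN differ, and cannot tell IFN from the kind of library.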

How the results depend on the processing

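The trend-removed fits, the 6-library fit of the guides with IFN (7054 genes), the thinned libraries and the DMSO control were chosen after the data had been seen; the other alternatives were planned. The cause of the changes below was not tested, except that a 2-fold threshold calls fewer genes by construction.

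RLE scaling left 592 of 594 named gene results on the same side of the threshold and in the same direction, DESeq2 576 of 593, no filter 585 of 594, guide 1 alone 328 of 351, guide 2 alone 320 of 351, guides as groups 340 of 351, the joint mouse fit 197 of 212 and thinning 65 of 70, with no reversal. The replicate block left 576 of 594 and lost 18 calls. It gave 53 genes for the interaction, 2 for the guides in HuH-7 without IFN, and 1609, 1765, 10958, 12810, 4967, 3931, 4593, 3832 and 5788 for knockout without IFN, knockout with IFN, IFN in sgNeg2 cells, IFN in knockout cells, EPZ-5676, Hepa1-6, Hep53.4, LLC and the mouse lines.

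At a 2-fold threshold the counts were 585 (knockout without IFN), 803 (with IFN), 5944 (IFN in sgNeg2 cells), 6577 (IFN in knockout cells), 41 (interaction), 429 (EPZ-5676), 216 (Hepa1-6), 235 (Hep53.4), 314 (LLC) and 834 (mouse lines). The guides then differed by 1 gene in HuH-7 without IFN (FOSB), 171 with IFN, 2 in Hepa1-6 (Cldn2 and Tnfrsf23), 3 in Hep53.4 (AW046200, C1rb and Srp54b) and 1 in LLC (Lcp1), named after their values were seen. Calls in common were 226 for knockout and EPZ-5676, 377 for knockout without and with IFN and 2 for the mouse lines.

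Knockout without and with IFN gave 4208 and 4182 genes with guides as groups, 3028 and 4359 with guide 1 alone, 3901 and 5069 with guide 2 alone, and 2897 and 1000 in 6-library fits. With the length and GC trend removed they gave 4411 and 3202 genes, which held 1750 of the 1863 and 1786 of the 2037 calls, and the guides with IFN gave 1935. The interaction then gave 1101 genes, which held 81 of the 83 calls, and left 27 of 33 named gene results on the same side of the threshold (6 others passed it). DESeq2 called 400 genes for the interaction and 112 between guides without IFN, where no filter gave 20. Of 93 list calls 36 held with an estimated correlation, and fry gave 144. With DMSO as the control 10641 genes were called for IFN, 7280 of them called in the same direction against sgNeg2.

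Leaving out 1 library gave 564 to 1670 genes for knockout without IFN, 960 to 2162 with IFN, 9630 to 9842 for IFN in sgNeg2 cells, 12203 to 12781 for IFN in knockout cells, 19 to 176 for the interaction, 4303 to 4659 for EPZ-5676, 2381 to 3976 in Hepa1-6, 3196 to 4970 in Hep53.4, 2519 to 4193 in LLC and 5120 to 6026 for the mouse lines. Between guides it gave 0 to 3688 in HuH-7 without IFN (edgeR, against 1876 at an unadjusted p under 0.05 with all libraries), 2369 to 4234 with IFN, 116 to 170 in Hepa1-6, 50 to 309 in Hep53.4 and 227 to 395 in LLC.

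Among the named genes alone, directions reversed with IFN for ZEB2 (2.94 without sgNeg2 replicate 1, lowest -6.6) and with DMSO as the control for RN7SK (0.65) and SLC18A2 (-1.06). The change of COL1A2 with IFN ended without sgNeg2 replicate 2 (0.00, lowest -8.3). In Hepa1-6 Col1a2 had 0.06 without sgNeg2 replicate 2 and a lowest value of -2.28. Depth limits the genes with few counts. Those with 0 counts in a group are given as bounds, and log2 changes of GBP5, CXCL9 and CD274 rest on few counts in sgNeg2 cells without IFN.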

Other observations

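Chosen after its result was seen was the test of the type of IFN; that of genes shared with the mouse lines was set before.

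Genes called in the same direction in human and mouse cells were sought among 9164 symbols measured in all comparisons. With knockout without IFN, EPZ-5676 and knockout in each of the 3 mouse lines 4 genes rose, and they are named after their values were seen. The number that independent lists would give was not computed for these counts. The 4 rises are therefore not shown to exceed it. CDKN1A, a cyclin-dependent kinase inhibitor gene, had log2 values of 0.50, 0.59, 0.11, 0.53 and 0.77 in HuH-7 knockout, EPZ-5676, Hepa1-6, Hep53.4 and LLC. The matrix gene MATN2 had 0.93, 0.55, 0.68, 1.21 and 0.33, the protease gene ADAMTS1 had 0.20, 0.26, 0.38, 0.50 and 0.35, and the cytochrome c gene CYCS had 0.40, 0.10, 0.47, 0.18 and 0.27. Knockout with IFN was not among these comparisons, and there CDKN1A had 1.05, MATN2 0.18, ADAMTS1 -0.11 and CYCS 0.06. The genes that fell in all of them were 25, DOT1L included, such as CDKN2C, another kinase inhibitor gene (-0.90, -0.35, -0.49, -0.22 and -0.70), the transcription factor gene NFIX (-0.59, -0.29, -0.61, -0.22 and -0.16), ZMYND8, a chromatin reader gene (-0.25, -0.31, -0.52, -0.43 and -0.14), and the catalase gene CAT (-0.54, -0.25, -0.34, -0.12 and -0.34).

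A hypothesis was that knockout raises the same genes in HuH-7 and in each mouse line. Genes that rose in HuH-7 without IFN rose more often than independent lists would give in 2 of 3 lines, Hepa1-6 (178 genes against 95.7, Fisher's exact two-sided adjusted p = 1.82e-17) and LLC (177 against 101, adjusted p = 3.7e-15), but not in Hep53.4 (138 against 128, adjusted p = 0.307). For falls the numbers were 207 against 114, 205 against 106 and 111 against 122 (adjusted p = 0.263 in Hep53.4), with 18 such tests made. In other HuH-7 settings Hep53.4 shared more than independent lists would give, for rises 164 against 117 with knockout under IFN (adjusted p = 2.08e-06) and 331 against 292 with EPZ-5676 (adjusted p = 0.00648), and for falls 193 against 142 and 734 against 539. The HuH-7 changes had a Spearman correlation with GC content of -0.371 for knockout without IFN, 0.063 with IFN and 0.004 with EPZ-5676. A trend on GC content was not tested in the mouse lines, and these overlaps were not computed with such a trend removed. Fisher's exact test also takes genes as independent, which they are not. The test without IFN therefore leaves the hypothesis open for all 3 lines.

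Genes called in both Hep53.4 and LLC were called in opposite directions in 1296 cases (766 if independent), and in 1148 cases with DESeq2 (541 if independent). Together 312 rose and 337 fell (340 and 429 if independent, Fisher's exact p = 0.0652 and 1.77e-08), but with DESeq2 282 and 293 did (263 and 276 if independent), and at 2-fold 19 rose together (1.79 if independent). Across genes, which are not independent replicates, the Pearson r was 0.107 and the Spearman rho -0.110 (0.114 and 0.015 with DESeq2).

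The type of IFN is not given in the sources used here. The median log2 change with IFN in sgNeg2 cells was 3.50 for 33 genes of the gamma response list alone and 1.88 for 56 genes of the interferon-stimulated list alone. The difference was 1.62 (two-sided permutation test over genes, p = 0.0122), in the direction that IFN of the gamma type may give. Genes are not independent replicates, so this p does not measure the spread between libraries. Against DMSO the difference was 1.07 for 28 and 48 genes. The medians were the same with the 4 genes at 0 counts in untreated cells set to their bounds. IFN of another type was not among the libraries, so the hypothesis rests on the fixed lists.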
